A study of Homo sapiens with 4 samples.

How the data were processed

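RNA bound to EXOSC10, the nuclear 3' to 5' exoribonuclease subunit of the RNA exosome, was recovered by immunoprecipitation from LM2-4175 cells and sequenced. LM2-4175 is a lung-metastatic derivative of the MDA-MB-231 breast carcinoma line, and the cells carried a doxycycline-inducible construct of the ceramide synthase CerS4. Cells were either untreated or given doxycycline at 5 µg/mL for 48 h, and each culture was immunoprecipitated with an EXOSC10 antibody or with control IgG. This gave 4 libraries in 4 groups, with 1 library per group. Libraries were made from total RNA with a SMARTer mRNA-seq kit, per the labels' protocols. The kit's strand setting and the counting rule are not given in the sources used here.

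The authors deposited a table of reads scaled to 1000000 per library (CPM), which was read as such from its values: each of the 4 columns reached that sum apart from a constant of 0.0001 on every entry, and most values were not whole. STAR and Partek, with genome build hg38 and no versions, are named per the submitters' processing notes. The table had 24015 entries for 12838 gene symbols, since several entries can carry the same symbol. The entries of a symbol were added up after the constant had been taken off. Every entry reached at least 10.0 reads in 1 library or more, so genes below that level were not analysed here. Of the symbols, 12545 matched a current symbol of the GRCh38.p14 gene table, 206 matched an older name only and 87 matched none. Coordinates are from that table, which is of the same build as hg38.

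The low values of each column lay on steps of 1 read, worth 0.269 CPM in the untreated IgG library, 0.236 CPM in the untreated EXOSC10 library, 0.132 CPM in the doxycycline IgG library and 0.181 CPM in the doxycycline EXOSC10 library. Reads were estimated as CPM divided by this step. Between 67.1% and 70.5% of the genes in a library had a sum within 0.05 of a whole read. The remaining genes held fractions, which arise when a read is divided between gene models, so whole reads could not be had for the table and no count model was used. The tests had been planned for counts and were replaced by limma on log2(CPM + 0.2).

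Scaling was by the trimmed mean of M values (TMM), trimming 30% of the ratios and 5% of the levels at each end, over the 4 libraries together. A ratio between 2 libraries is the log2 ratio of scaled CPM with a pseudocount of 0.2 CPM, about 1 read. This scale understates the ratio of low genes. Each ratio has an exact Clopper-Pearson 95% interval on the estimated reads. For the change of enrichment the interval comes from the summed reciprocal reads. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules and there is no replicate. A gene was counted as higher or lower when its 2 libraries held at least 100 reads together and the ratio was at least 2-fold. The change of enrichment needed 100 reads in each antibody's pair of libraries. The number that counting error alone would give was drawn 20 times from pooled profiles. A fold against a library with no read was taken against a floor of 3 reads in that library and is a lower bound.

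A pair of additive tests used all 4 libraries, 1 for the antibody with treatment as covariate and 1 for doxycycline with antibody as covariate, by limma with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. They left 1 residual degree of freedom and included genes with at least 10 reads in at least 2 libraries. Nothing in the labels says that the libraries came from separate cultures of a group, and in these tests the other factor stands in for replication.

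Before the data were examined, 26 gene lists were fixed: RNA exosome, stress granule proteins, sphingolipid metabolism, Hedgehog, TGF-beta and Wnt signalling, immune checkpoint and antigen presentation, interferon-induced genes, epithelial-mesenchymal transition, lung metastasis genes, mitochondrially encoded transcripts, oxidative phosphorylation, ATF4 targets, unfolded protein response, cholesterol synthesis, fatty acid synthesis and lipid storage, ribosomal proteins, small nucleolar RNA host genes, nuclear-retained long non-coding RNAs, histone genes, immediate early and AU-rich mRNAs, cell cycle, p53 targets, KRAB zinc fingers, blood and immune markers, and fibroblast, endothelial and breast epithelial markers. A list's median covers members with at least 20 reads in the libraries compared, and its percentile is among 10000 random lists of the same size matched on mean expression in 20 bins. The rule for named genes, also fixed then, took CERS4, CD274, CAPRIN1 and EXOSC10 first; the genes whose interval bound nearest 0 lay farthest from it (10 each way for EXOSC10 with doxycycline, 8 for the change of enrichment, 5 for IgG with doxycycline, 8 for EXOSC10 over IgG in both treatments); the 5 smallest p each way in the tests; up to 4 members of each list; and SHH, TGFBR1, SMO, GLI1, GLI2 and CTNNB1 whatever their value. Genes of the same ranks restricted to those with whole reads in all 4 libraries were added after the data had been seen. Some genes that these rules pick are not reported here.

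On simulated reads the size rule recovered 100.0% of 75 genes changed 4-fold and 55.0% of 80 genes changed 2-fold between the EXOSC10 libraries, with 0 unchanged genes called among 4951 genes. In a simulation of the antibody test over 10359 genes, limma recovered 98.0% of genes changed 4-fold and 71.0% of those changed 2-fold, with 5 unchanged genes called. The first simulation held counting error only, and the second a small added spread between libraries. In the data the SD of log2 ratios was 0.667 for the EXOSC10 pair and 0.763 for the change of enrichment. The simulated rates are therefore for quieter data and do not carry over to these libraries. Alternatives covered the scaling, the minimum of reads, thinning to the smallest library, ribosomal RNA genes, the pseudocount, whole reads, and each library left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.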

Results

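The libraries recorded which RNAs came down with EXOSC10 or with control IgG in LM2-4175 cells without and with doxycycline, which induces CerS4, a ceramide synthase. The study asked how mRNA degradation linked to the PD-L1 and Caprin-1 complex is altered when lipid metabolism changes, and its primary comparison was the EXOSC10-bound RNA of untreated against doxycycline-treated cells. There was 1 library for each of the 4 combinations, so no difference between single libraries has a replicate check, and no p-value is given for one. The untreated IgG library held 3723371 estimated reads, the untreated EXOSC10 library 4233653, the doxycycline IgG library 7575200 and the doxycycline EXOSC10 library 5511242.

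Most reads lay on ribosomal RNA genes: 71.7% in the untreated IgG library, 75.8% in the untreated EXOSC10 library, 83.8% in the doxycycline IgG library and 56.3% in the doxycycline EXOSC10 library. This left 1053012, 1023376, 1229756 and 2408191 reads, in the same order, on other genes, and only these set the precision for mRNAs. The TMM factors ran from 0.453 in the doxycycline IgG library to 2.50 in the doxycycline EXOSC10 library. Long non-coding RNAs made up 0.878% and 1.23% of the non-ribosomal reads with EXOSC10 and 0.459% and 0.456% with IgG, untreated and with doxycycline respectively.

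Of the genes named in the design, CERS4 and CD274 (PD-L1) had no entry analysed here, so the induction of the construct could not be checked. CAPRIN1, which encodes an RNA-binding protein of stress granules, had 826 reads in the untreated IgG library, 499 in the untreated EXOSC10 library, 852 in the doxycycline IgG library and 1251 in the doxycycline EXOSC10 library. Its EXOSC10 ratio of doxycycline over untreated was -0.07 on the log2 scale (95% interval -0.22 to 0.08), which does not exclude equality. EXOSC10 mRNA itself had 6, 15, 21 and 78 reads in the same order, and its EXOSC10 ratio was 0.93. SHH and GLI1 had no entry analysed here. In the EXOSC10 libraries, TGFBR1 was at 0.57 (0.18 to 0.99), SMO, the Hedgehog signal transducer, at -0.26 (-0.80 to 0.29), and CTNNB1, which encodes beta-catenin, at -0.45 (-0.53 to -0.36). GLI2 had 0 reads untreated and 54.4 with doxycycline, at least 6.89-fold higher, but it lay below the minimum of 100 reads and held fractions of reads.

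In the EXOSC10 libraries, doxycycline over untreated, WNT7A, a secreted Wnt ligand, differed most on the lower side: 152 reads untreated and 37.0 with doxycycline, a log2 ratio of -3.34 (-4.00 to -2.91), or 10.1-fold lower after scaling. WNT7A lies on chromosome 3 from 13816258 to 13880071 (GRCh38) and its reads were whole. Lower as well were ATP6V1H, a subunit of the vacuolar proton pump (-2.68), ZEB2, a transcription factor of epithelial-mesenchymal transition (-2.00, -2.33 to -1.71), and ANKHD1 (-2.21). ATP6V1H, ZEB2 and ANKHD1 held fractions of reads in 1 library or more. The ribosomal RNA genes RNA28SN3 (-1.82, with all 18S and 28S genes together at -1.46) and RNA5-8SN1 to RNA5-8SN5 (-1.78 to -1.77) were lower too. The genes on the higher side whose intervals lay farthest from 0 included ANKHD1-EIF4EBP3 (5.68), INPP4A (4.68), AMZ2 (4.54), GSTM3 (4.16), CHEK1, a checkpoint kinase (4.16), and EHF, an epithelial transcription factor (3.60). TIMM23B-AGAP6 was at least 19.0-fold, YIPF1 at least 14.3-fold, FAM72B at least 13.4-fold and CHTF8 at least 12.9-fold higher, since each had no full read in the untreated library. These 10 genes on the higher side all held fractions of reads, ANKHD1-EIF4EBP3 and TIMM23B-AGAP6 are read-through transcripts that overlap their neighbours, and FAM72B has near-identical copies, so their ratios are uncertain. With overlapping genes summed, a step chosen after the data were seen, ANKHD1 and ANKHD1-EIF4EBP3 were at 0.09, TIMM23B-AGAP6 with TIMM23B and AGAP6 at 1.05, and CHTF8 with HAS3 and DERPC at -0.24. Neither the fall of ANKHD1 nor the rise of its read-through is therefore shown. Summed in the same way with the 45S genes that overlap them, RNA5-8SN1, RNA5-8SN2, RNA5-8SN3 and RNA5-8SN5 were at -0.81, -0.71, -0.73 and -0.79, short of 2-fold. RNA28SN3 with RNA45SN3 was at -1.79.

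Among genes with whole reads in all libraries, a restriction chosen after the values were seen, the interval farthest from 0 on the higher side was that of NDC80, a kinetochore protein, with 5 reads untreated and 162 with doxycycline (3.37, 2.37 to 5.26). Also on this side were GGH, gamma-glutamyl hydrolase (3.50, 2.32 to 6.20), NOL12, a nucleolar RNA-binding protein (3.03), the small nucleolar RNA host gene SNHG7 (2.74), OSTM1 (2.80), SEMA6B (2.41), MRPL33 of the mitochondrial ribosome (2.52), ZNF70 (2.41) and CLBA1 (2.36). On the lower side, WNT7A was followed by RPS6KA1, a kinase downstream of ERK (-2.03), MFSD14B (-1.98), the semaphorin and VEGF co-receptor NRP2 (-1.73), the transcriptional co-regulator CITED2 (-1.51, -1.64 to -1.39), the AP-1 subunit JUND (-1.55, -1.72 to -1.39), the histone gene H2AC6 (-1.84), XYLT2 (-1.76), IGFBP7 (-1.50) and ENTPD4 (-1.82).

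**Figure D1:**
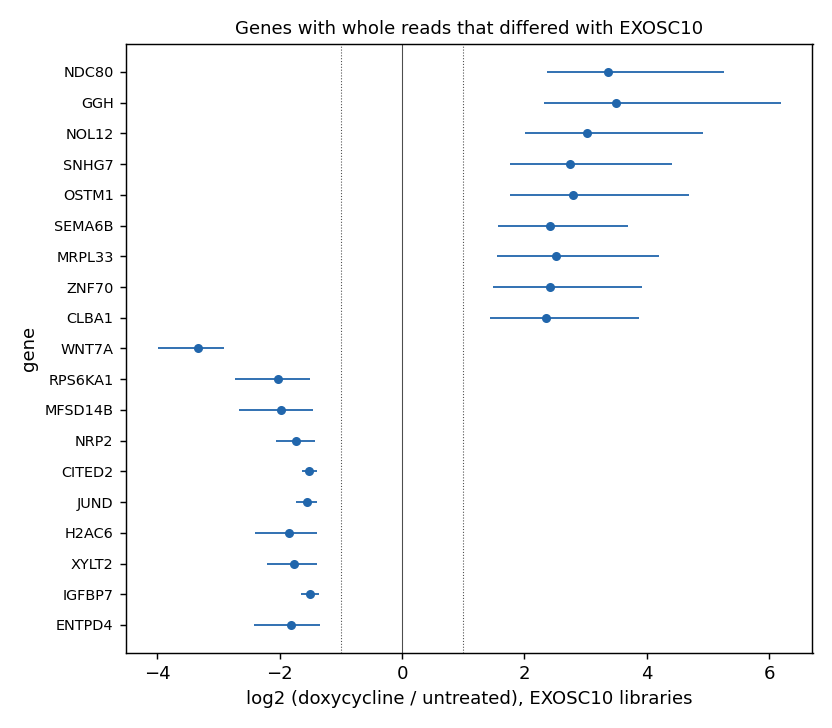
Log2 ratio of doxycycline over untreated in the EXOSC10 libraries (x axis) for 19 genes with whole reads (y axis); points are ratios of 1 library to 1 library and bars are 95% counting intervals. The dotted lines mark 2-fold. WNT7A stands apart at -3.34, and the genes on the higher side have wide intervals because the untreated library held few reads of them.

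In all, 399 genes were higher and 262 lower by at least 2-fold among 6584 genes with 100 reads, where counting error alone gave a median of 2 genes. The direction of this split depends on the scaling and on depth. It was 3150 higher and 8 lower with total counts, which move every ratio by 1.02, 339 and 374 with median-of-ratios factors, 490 and 188 with the upper quartile, and 598 and 148 with the total of non-ribosomal reads. Ratios between -1.02 and 0 in this comparison therefore turn positive with total counts, and 12 of 24 list medians change sign. A minimum of 500 reads left 5 genes higher and 40 lower. Thinning every library to the smallest total gave 233 higher and 195 lower. With thinning to the smallest total of non-ribosomal reads, more genes were lower than higher in each of 20 draws. The first draw gave 69 higher and 355 lower, and the second 98 and 190.

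Among the gene lists fixed beforehand, stress granule proteins lay on the lower side, with a median of -0.41 over 20 members, at percentile 2.11 of random lists, although 0 of the 20 reached 2-fold. ELAVL1 (-0.97), FXR2 (-0.95), FMR1 (-0.88) and DDX3X (-0.86) were lowest. The random lists are matched on expression only, and 16 of the 20 members were also called lower in the limma test of EXOSC10 over IgG. The 1619 genes whose mean EXOSC10 over IgG ratio lay below -1 had a median of -0.43 in this comparison. The list's median is thus close to that of such genes in general. Fatty acid synthesis and lipid storage had a median of 0.25 at percentile 99.7: 0 of 23 members with 100 reads were 2-fold higher, LPIN2 was at 0.59, and the lipid droplet protein PLIN2, at -1.53, was the only member 2-fold lower. KRAB zinc fingers were higher, with a median of 0.69 at percentile 99.0, and 5 of 12 members with 100 reads were at least 2-fold higher, among them ZNF282 (1.46), ZNF33A (1.39) and ZNF37A (1.17). The list as fixed also held ZNF292 (1.31), a zinc finger protein without a KRAB domain; without it, a choice made after the data were seen, the median was 0.69 at percentile 98.7, and 4 of 11 members were at least 2-fold higher. The stress granule median turns positive with total counts, while the percentile, which compares genes within the same libraries, was then 1.08; with a minimum of 100 reads it was 3.16.

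The other lists stayed inside the central 95% of random lists or close to its edge. Interferon-induced genes had a median of -0.18 at percentile 2.56 over 13 members, with STAT2 at -0.22. Medians were 0.64 for p53 targets (percentile 97.2; BAX 2.34, FDXR 2.10, MDM2 0.73, RRM2B 0.70), 0.26 for cholesterol synthesis (97.0; PMVK 1.60, HMGCS1 0.83, INSIG1 0.70) and -0.09 for ribosomal proteins (97.0; 0 of 78 at 2-fold; RPL17 -0.90, RPL27A -0.88). For sphingolipid metabolism, the pathway of the construct, the median was 0.18 at percentile 83.3, and KDSR, which makes dihydrosphingosine, was higher (1.09, 0.51 to 1.78), followed by the glucosylceramide synthase UGCG (0.85), SGPL1 (0.63) and SMPD4 (-0.74). The RNA exosome list was at 0.34 (percentile 86.3), with 2 of 8 members at least 2-fold higher, ZCCHC8 of the nuclear exosome targeting complex (1.38) and EXOSC2 (1.01), while TENT4A was at -0.82 and MTREX at 0.35. TGF-beta signalling was at -0.15 (percentile 21.5), with SMAD7 (-1.36), INHBA (-1.18) and SKIL (-1.14) among 4 lower members and ACVR1 (1.27) as the 1 higher. Wnt signalling was at -0.18 (15.4), with WNT7A as its 1 lower member, FZD1 at 0.97, TCF7L2 at -0.95 and AXIN1 at -0.88. Hedgehog signalling was at -0.15 (22.6; GLI3 -0.38, SUFU -0.24, DISP2 -0.20).

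Immune checkpoint and antigen presentation genes had a median of 0.10 (percentile 63.1), with the ecto-nucleotidase NT5E (1.49) and the PD-L1 stabiliser CMTM6 (0.78) on the higher side, TAPBP at 0.53 and the checkpoint ligand CD276 at -0.92. Epithelial-mesenchymal transition genes were at -0.12 (39.5; ITGA5 1.59, ZEB2 -2.00, KRT8 -0.80, ZEB1 0.69), lung metastasis genes at 0.36 (83.1; ID1 -1.07, ROBO1 0.93, MAN1A1 -0.29, SPARC 0.08), and short-lived immediate early and AU-rich mRNAs at -0.20 (16.8; JUND -1.55, BTG1 -0.93, GADD45A -0.88, NFKBIA -0.81). ATF4 targets were at -0.11 (35.9), with PHGDH of serine synthesis at 1.63, CEBPB at -0.98, GARS1 at -0.89 and SLC7A11 at 0.69. The unfolded protein response was at -0.03 (76.4; DNAJC3 1.08, DNAJB11 0.80, HSPA5 -0.77, EDEM1 -0.61), the cell cycle list at 0.11 (90.1; CCNA2 1.18, KIF11 1.15, KIF20A 0.89, PLK1 -0.88), small nucleolar RNA host genes at 0.33 (84.1; SNHG7 2.74, SNHG3 1.27, DANCR 0.78, TAF1D 0.48) and histone genes at 0.24 (48.1; H2AC6 -1.84, H2AC16 -1.62, H4C15 1.29, H2BC5 0.82). The list of nuclear-retained long non-coding RNAs was at 0.14 (93.9; RPPH1 -0.78, RN7SK -0.65, MALAT1 0.59). As fixed, it also held RN7SL1 (-0.95) and RN7SL2, cytoplasmic RNAs of the signal recognition particle, and was at 0.19 (93.4) without them, a choice made after the data were seen. Oxidative phosphorylation genes were at -0.00 (78.8), with UQCRFS1 at -1.48, NDUFA2 at 1.40, COX7C at 0.83 and ATP5F1B at -0.82. Markers of fibroblasts, endothelium and breast epithelium were at -0.20 (13.5; COL1A2 -1.38, COL1A1 -0.81, KRT14 -0.80, FOXA1 0.68). Of 24 blood and immune markers, 2 had entries, CD68 (-0.87) among them, and the mitochondrially encoded transcripts had no entry analysed here.

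With control IgG, doxycycline over untreated, CASK, a membrane scaffold kinase, had 50 reads untreated and 475 with doxycycline (2.87, 2.46 to 3.33). Also higher were RN7SL1 (2.02), BIRC6 (1.94), VLDLR (2.37) and WNT7A (1.96, 1.65 to 2.30). DLG4 (-4.10), TMEM243 (-3.86), ELAPOR2 (-4.05), DNM1 (-2.74) and the cell cycle kinase gene CDK6 (-2.47, -2.89 to -2.09) were lower. CASK, BIRC6, WNT7A and CDK6 had whole reads; the others held fractions of reads, and DLG4, TMEM243 and DNM1 overlap the genes ACADVL, DMTF1 and CIZ1. The nuclear-retained long non-coding RNAs (0.47, percentile 99.8; 0.36 and 98.0 without RN7SL1 and RN7SL2; -0.18 with total counts) and the p53 targets (0.93 over 8 members, percentile 99.3) lay above nearly all random lists, though the latter fell to percentile 66.0 when the libraries were thinned to equal totals. Of 3027 genes, 90 were higher and 104 lower, against a median of 0 from counting error. The split was 12 and 803 with total counts, which move every ratio by -0.66, 122 and 73 with the total of non-ribosomal reads, and 47 and 130 after thinning.

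The doxycycline ratios of the EXOSC10 and IgG libraries had a Pearson's r of -0.06 and a Spearman's rho of 0.01 across the 2946 genes with 100 reads in both pairs. Pearson's r was -0.22 with a minimum of 500 reads and -0.13 after thinning; genes are not independent replicates. Among these genes, 22 were 2-fold higher and 157 lower in the EXOSC10 pair, unlike the split over all genes tested there, and 38.5% of the 179 had the same sign in the IgG pair, where independent signs would give 53.5%. The share depends on the scaling: it was 9.93% with total counts, where independent signs would give 8.66%. It was 40.2% against 47.5% with the total of non-ribosomal reads, which also leaves out the ribosomal RNA genes (2928 genes). MYO9A and RALGAPA1 were higher with both antibodies, where independent lists would share 0.627 genes, and H2AC16, MEA1, SEPTIN8, SPRYD3 and STK11 lower with both, against 4.80; these 7 were named after their values were seen.

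**Figure D2:**
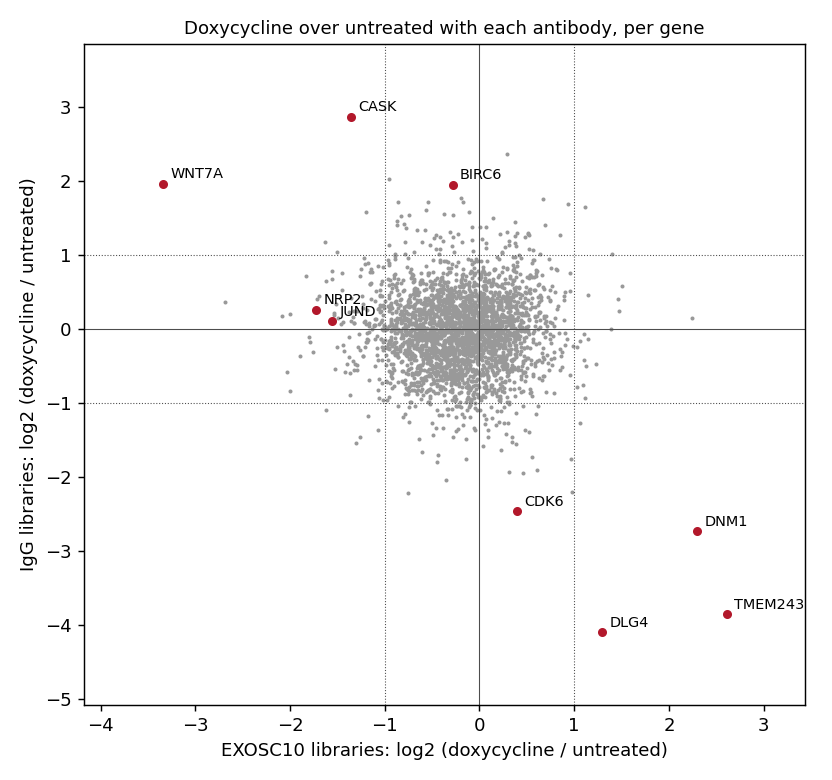
Log2 ratio of doxycycline over untreated per gene in the EXOSC10 libraries (x axis) and in the IgG libraries (y axis), 1 library per group, for 2928 non-ribosomal genes with 100 reads in both pairs (grey); red points are named genes and dotted lines mark 2-fold. WNT7A and CASK lie in the upper left.

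EXOSC10 over IgG separated genes far more than doxycycline did, and in the same way in both treatments, with Pearson's r of 0.79 and Spearman's rho of 0.81 over 3599 genes in pairs that share no library. Among the highest in both treatments were TONSL (1.87 untreated, 1.54 with doxycycline), the tRNA 3' processing nuclease ELAC2 (1.50, 1.37), LAS1L of ribosomal RNA processing (1.58, 1.90), ELFN2 (2.01, 1.25), SDHA of the respiratory chain (1.23, 1.70), the phosphatidate phosphatase LPIN1 (1.48, 1.75) and CEP55 (1.51, 1.37). Among the lowest were VIM-AS1, which had 1279 reads with IgG and 0 with EXOSC10 untreated, at least 839-fold lower, and -5.72 with doxycycline, PCBP2, a poly(C)-binding protein (-3.86, -3.03), APBB1 (-3.51, -4.05), GRIK5 (-3.77, -3.10), PABPC3 (-3.13, -2.79), GLUD2 (-2.96, -2.88) and PABPC1, the cytoplasmic poly(A)-binding protein (-2.87, -2.70). VIM-AS1 overlaps VIM on the other strand and cannot be told apart from it without strand, and PABPC3 and GLUD2 are near-identical copies of PABPC1 and GLUD1. CTNNB1 behaved like PABPC1 (-2.98, -2.72), and SMO was also lower (-2.47, -2.99).

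Untreated, 194 genes were higher and 1305 lower among 3619; with doxycycline, 882 were higher and 1670 lower among 6279. Only 36 genes were higher and 1117 lower in both. These splits rest on the scaling: they became 1133 and 523 untreated and 5080 and 34 with doxycycline with total counts, which moved the ratios by 0.79 and 2.47, and 1385 and 314, and 3280 and 651, with the total of non-ribosomal reads. With the upper quartile the doxycycline split was 1263 and 1458, and with a minimum of 20 reads it was 2864 and 2158. Whether a gene is above or below IgG in absolute terms is therefore open, and the order of genes is what the libraries show. With doxycycline, CAPRIN1 was at -1.45 with TMM and at 1.01 with total counts.

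Ribosomal proteins (0.35 untreated and 0.39 with doxycycline) lay above every random list in both treatments, and the nuclear-retained long non-coding RNAs (0.63 and 0.44) did so untreated and were at percentile 97.9 with doxycycline. Without RN7SL1 and RN7SL2 the latter were at 99.97 and 96.6, and also without NORAD, CYTOR and OIP5-AS1, found largely in the cytoplasm as well, at 99.92 and 94.1. The random lists matched to ribosomal proteins had medians of -1.15 and -1.29, and those matched to the nuclear-retained RNAs -1.03 and -0.47. Ratios of all genes, as the mean of the treatments, peaked between 0.25 and 0.75. Ribosomal proteins thus lay near that peak. They were less often far below IgG than genes of like level, and not higher than most genes. Oxidative phosphorylation (0.46 and 0.50; percentiles 99.6 and 99.8), fatty acid synthesis and lipid storage (0.36 and 0.64; 98.8 and 99.9) and ATF4 targets (0.52 and 0.50; 99.7 and 99.3) were also high in both. MALAT1 was at 0.77 and 0.60 and NEAT1, named after its value was seen, at 0.69 and 0.53. Stress granule proteins were low with doxycycline (-2.10, percentile 1.87; 16 of 20 members at least 2-fold lower), and at -1.50 and percentile 17.3 untreated. TGF-beta signalling (-0.85, percentile 1.02) and the RNA exosome list (-0.59, 0.54) were low untreated, at percentiles 5.57 and 89.4 with doxycycline. Epithelial-mesenchymal transition genes were high with doxycycline (0.61, percentile 99.5). Untreated, the negative medians of the TGF-beta and RNA exosome lists turn positive with the total of non-ribosomal reads (0.14 and 0.39), the latter also with total counts (0.16). That of the stress granule proteins with doxycycline turns positive with total counts (0.36). With a minimum of 100 reads for members, percentiles fell inside the central 95% for ATF4 targets (90.6 untreated, 96.4 with doxycycline), and untreated for oxidative phosphorylation (83.8), TGF-beta signalling (6.19) and the RNA exosome list (15.7). After thinning they did so with doxycycline for ATF4 targets (94.7), epithelial-mesenchymal transition (90.6) and the nuclear-retained long non-coding RNAs (96.4). With total counts they did so with doxycycline for ATF4 targets (95.4) and the nuclear-retained long non-coding RNAs (94.4). Over the 5 comparisons, 21 of 120 list medians lay outside the central 95%, where chance alone gives 6.

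**Figure D3:**
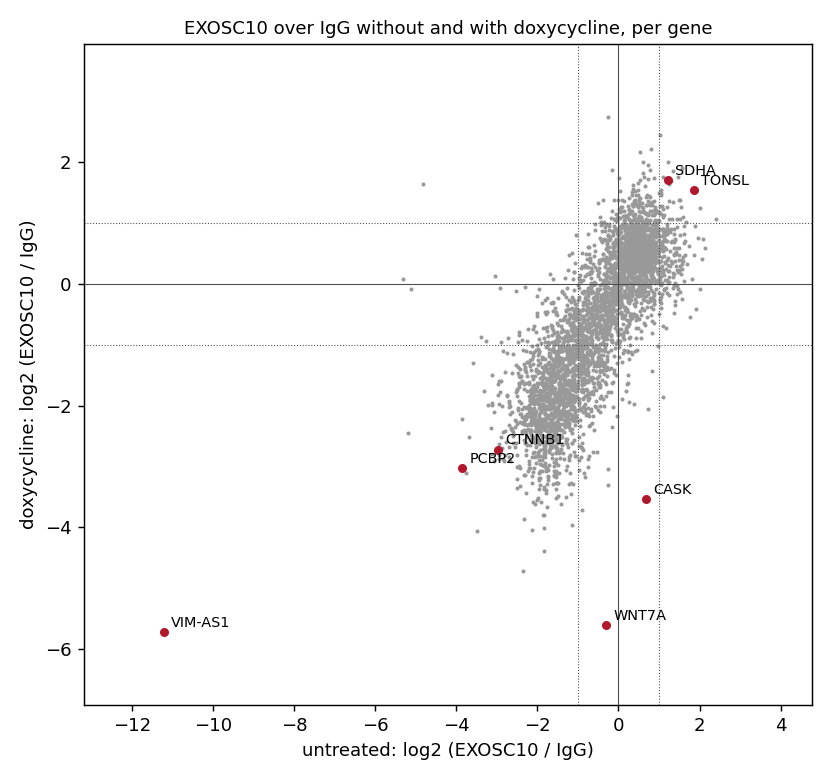
Log2 ratio of EXOSC10 over IgG per gene, untreated (x axis) and with doxycycline (y axis), 1 library per group, for 3581 non-ribosomal genes with 100 reads in both pairs (grey); red points are named genes and dotted lines mark 2-fold. The points are densest near 0.5 on both axes and run down from there without a gap, and WNT7A and CASK lie well below the diagonal.

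The limma test of EXOSC10 over IgG across both treatments called 131 genes higher and 1523 lower at an adjusted p of 0.05 among 9594. Among the smallest p on the higher side were those of SDHA (log2 1.46, limma adjusted p 0.0105), HSD17B4, a peroxisomal beta-oxidation enzyme (3.15, SE 0.649, limma adjusted p 0.0106), XRCC3 (2.90) and ELFN2 (1.63). On the lower side they included those of GLUD2 (-2.92, SE 0.243, limma adjusted p 0.00168), SUZ12, a Polycomb subunit (-2.81), NIPBL, the cohesin loader (-2.80), and CTDNEP1 (-2.79). Of the 20 stress granule proteins, 16 were lower and 1 higher, or 16 and 2 adjusted over the list alone. Of 28 TGF-beta genes, 10 were lower, or 11 lower and 1 higher over the list alone, and of 78 ribosomal protein genes 16 were lower and 1 higher, or 16 and 2. Against random lists matched on expression, a comparison chosen after the data were seen, the number called lower was high for stress granule proteins (percentile 99.4) and below every random list for ribosomal proteins, of which 20.5% were called where random lists had a mean of 54.4%. It was also low for the nuclear-retained long non-coding RNAs (0 of 13), the unfolded protein response (1 of 20), cholesterol synthesis (0 of 21), lung metastasis genes (0 of 11), the cell cycle (2 of 39), fatty acid synthesis and lipid storage (3 of 26) and oxidative phosphorylation (4 of 54), at percentiles of 0.005 to 2.05. The other lists lay inside the central 95%, among them TGF-beta signalling (96.5), Wnt signalling (8 of 36, 46.6), immediate early and AU-rich mRNAs (8 of 29, 41.3) and epithelial-mesenchymal transition (5 of 22, 16.6). Calls on the higher side were above the central 95% for fatty acid synthesis and lipid storage alone (2 of 26, percentile 98.2). Without treatment as covariate, leaving out the untreated or the doxycycline EXOSC10 library gave 0 calls. The folds stayed: the genes called lower had a median of -2.01 or -1.59, against -1.81 with all libraries, and those called higher 2.35 or 2.39, against 2.37. The median SE of the called genes was 0.328 or 0.324, against 0.309. The total degrees of freedom fell from 8.55 to 3.25 or 3.22. Each of these fits had 1 residual degree of freedom, so the fall was in the part that limma estimates from the variances of all genes. Without an IgG library the total was 15.98 or 16.05. The calls thus depended on which antibody's pair of libraries supplied the error. Leaving out an IgG library gave 453 higher and 1275 lower or 576 higher and 1440 lower. The split was 66 and 1471 with median-of-ratios factors, 474 and 1491 with the upper quartile, 377 and 1760 with a pseudocount of 1 CPM, 377 and 1808 without a filter, 514 and 6 with total counts and 3277 and 581 with the total of non-ribosomal reads.

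The limma test of doxycycline across both antibodies called 0 of 9594 genes, with 444 genes, or 4.63%, at an unadjusted p under 0.05 and a smallest adjusted p of 0.850. In this test a doxycycline difference that is not shared by both antibodies counts as error. The 0 calls therefore do not show that the EXOSC10 libraries were alike with and without doxycycline. No list had a call over all genes, and adjusted over the list alone 1 histone gene was lower. Leaving out the untreated EXOSC10 library, without antibody as covariate, gave 19 higher and 4 lower genes.

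The change of enrichment with doxycycline, the EXOSC10 over IgG ratio with doxycycline minus that without, was lowest for WNT7A (-5.30, -5.91 to -4.70) and CASK (-4.22, -4.75 to -3.70). RNA5-8SN1 to RNA5-8SN5, the 5.8S ribosomal RNA genes, were at -3.36 to -3.33 and RN7SL1 at -2.97. The higher side was led by TMEM243 (6.47), DLG4 (5.40), DNM1 (5.04), CDK6 (2.86, 2.32 to 3.40), the Wnt receptor gene FZD1 (3.18), IGFBP4 (2.51, 2.16 to 2.87), POTEJ (2.73) and VPS25 (2.33). TMEM243, DLG4 and DNM1 held fractions of reads and overlap other genes, so their values are uncertain. CDK6, IGFBP4 and FZD1 were at -2.47, -1.90 and -2.20 in the IgG pair and at 0.40, 0.61 and 0.97 in the EXOSC10 pair. KRAB zinc fingers were high (1.01 over 10 members, of which 2 had 100 reads; percentile 99.8, 97.3 after thinning and 99.5 without ZNF292), as were ribosomal proteins (0.04, percentile 99.2; -0.02 with median-of-ratios factors). In all, 140 genes were higher and 321 lower among 2946, or 2275 and 11 with total counts, which move each value by 1.67, and 2683 and 2257 with no minimum of reads.

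Reads on the 45S precursor genes and on the mature ribosomal RNA genes differed in proportion. Reads on the 45S precursor genes per 1000 reads on 18S and 28S genes were 3.60 with IgG and 7.21 with EXOSC10 untreated, and 1.91 with IgG and 17.5 with EXOSC10 under doxycycline. As shares of all reads the 45S genes held 0.256%, 0.538%, 0.159% and 0.964% in the same order. On the TMM scale used for genes, EXOSC10 over IgG was 0.28 untreated and 0.13 with doxycycline for 45S, and -0.73 and -3.06 for 18S and 28S together. In the EXOSC10 pair, 45S was at -0.18 with TMM, but 1.79-fold higher with doxycycline as a share of all reads, so its direction there flips with the scaling. Copies of the ribosomal RNA genes are near-identical and were summed. The 45S genes overlap genes of mature ribosomal RNA, and how reads were divided between them is not known. Reads on the 45S genes can therefore include mature ribosomal RNA, and the proportion can depend on that division.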

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

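The tests of explanations in this part were all chosen after the results, or part of the values behind them, had been seen. The following genes were at least 2-fold on opposite sides with doxycycline in the EXOSC10 and the IgG libraries; with 1 library per group the difference was not tested. The EXOSC10 ratio minus the IgG ratio was -5.30 for WNT7A, -4.22 for CASK, -2.80 for MYH10, -2.78 for FYN and -2.54 for SHOC2, which were lower with EXOSC10 and higher with IgG. It was -3.33 for the 5.8S ribosomal RNA gene RNA5-8SN4. In the other direction it was 6.47 for TMEM243, 5.40 for DLG4, 5.04 for DNM1 and 2.33 for VPS25. If the pairs were independent, 4.48 genes would be lower with EXOSC10 and higher with IgG and 0.672 the other way, where 10 and 4 were seen. Of the 10, 5 are copies of the 5.8S gene. Of the 4, TMEM243, DLG4 and DNM1 held fractions of reads and overlap other genes, so neither number shows an excess.

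The first pattern is the wide spread of EXOSC10 over IgG ratios across genes, with a peak between 0.25 and 0.75 and a broad lower side that runs down to about -2.5 without a gap. Few amplified molecules in the IgG libraries are argued against as the whole cause. The ratios untreated and with doxycycline, from pairs that share no library, had a Pearson's r of 0.79. The IgG libraries also resembled each other (Pearson's r of 0.926 across 5109 genes) more than the EXOSC10 libraries did (0.888). As the EXOSC10 pair holds any doxycycline difference too, that comparison alone does not decide. How far few molecules add to the spread was not tested. Reads divided between overlapping genes do not account for it as a whole, as genes with whole reads kept 92.4% of the spread. Reads from another organism, which carry differences from the human sequence and might land more often on human copies of a gene, stay open. The copy's share was higher with IgG in both treatments in 18.1% of 105 parent and pseudogene pairs, but 9 copies had no read in either IgG library and none lacked reads in the doxycycline EXOSC10 library, so this share does not decide. In 37 pairs whose copy would have at least 10 reads in every library at its mean share, it was 40.5% (Clopper-Pearson 95% interval 24.8% to 57.9%), between the bounds set for either outcome (25% and 75%). It ran from 19.6% to 52.2% with minimums of 1 to 20 reads. RNA of other human cells cannot be told apart from binding to EXOSC10: ribosomal protein genes, which every cell uses, had 79.3% of the spread of all genes, between the bounds set for either outcome (50% and 80%). Their median lay 0.80 above that of all genes untreated and 0.35 above it with doxycycline, outside the 0.25 that RNA of other cells was to give. This does not decide, because the median of all genes takes in the broad lower side to be explained. Untreated, that median was -0.45, and 36.1% of genes were at least 2-fold lower. Binding to EXOSC10, the biological difference of the design, stays open and was not tested apart from these.

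The second pattern is the difference between the EXOSC10 libraries with doxycycline. Depth is argued against as its whole cause. After every library had been thinned to the smallest total of non-ribosomal reads, a median of 288 genes were 2-fold, where counting error gave at most 10. The number ran from 281 to 431 over 20 draws, by the library that TMM took as reference. In each draw more genes were lower than higher, unlike the 399 and 262 before thinning. Whether they were the same genes as before thinning was not tested. How far depth adds to the 661 genes was not tested. Reads divided between genes are argued against as the whole cause too: 8.19% of genes with whole reads were 2-fold, against 12.5% of the others. A different share of IgG-type RNA in the EXOSC10 libraries cannot be told apart from an effect of doxycycline, because Spearman's rho of the doxycycline ratio with the mean EXOSC10 over IgG ratio was 0.394 across 4500 genes, between the bounds set for either outcome (0.2 and 0.5). The 1619 genes whose mean EXOSC10 over IgG ratio lay below -1 had a median of -0.43 with doxycycline, and the 1665 genes above 0 a median of 0.03. The same ratio enters both sides of this correlation. An effect of doxycycline on EXOSC10 binding stays open and was not tested, as there is 1 library per group. All 4 libraries are immunoprecipitates, and none holds RNA of the cells before that step. A changed level of an RNA in the cells therefore cannot be told apart from changed binding in the doxycycline ratios.

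The third pattern is the greater number of 45S precursor reads per mature ribosomal RNA read with EXOSC10. Recovery of reads on the 45S genes beyond that of other RNA is argued against, since their ratio lay at percentile 71.5 of genes untreated and at 52.9 with doxycycline. As these genes overlap those of mature ribosomal RNA, this does not decide it for the precursor itself. How the division of reads between them adds to the pattern was not tested. A lower amount of mature ribosomal RNA is a candidate explanation with doxycycline, where the 18S and 28S ratio lay at percentile 1.42 of genes; untreated it lay at 44.0, so the untreated difference stays open.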

How the results depend on the processing

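The alternatives with the total of non-ribosomal reads, whole reads, the 1 CPM pseudocount in the counts of genes, libraries left out, thinning to non-ribosomal reads, list members left out, total counts in the limma tests, and the scalings of the shared sign were chosen after seeing the data. Numbers of 2-fold genes follow in the order EXOSC10 with doxycycline, IgG with doxycycline, EXOSC10 over IgG untreated, the same with doxycycline, and change of enrichment; the first were 661, 194, 1499, 2552 and 461. A minimum of 20 reads gave 2744, 1170, 3394, 5022 and 1932, no minimum 4008, 3917, 5678, 6363 and 4940, and a minimum of 500 reads 45, 42, 479, 775 and 104, as more or fewer genes were tested. Whole reads only, which also tests fewer genes, gave 306, 97, 827, 1325 and 255. Total counts, which shift all ratios, gave 3158, 815, 1656, 5114 and 2286. The total of non-ribosomal reads gave 3931 for EXOSC10 over IgG with doxycycline, and thinning gave 428 for EXOSC10 with doxycycline, or a median of 288 when thinned to the smallest total of non-ribosomal reads. The remaining counts of these comparisons stayed within 1.5 times the first.

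The antibody test called 1654 genes. It called 520 with total counts, 3858 with the total of non-ribosomal reads and 975 with whole reads only, which tests fewer genes. With either EXOSC10 library left out, the folds of the called genes stayed and the degrees of freedom that limma estimates fell. The doxycycline test called 0. It called 4 without a filter, 11 with total counts, and 0 to 23 with a library left out, with 23 without the untreated EXOSC10 library. With a library left out the other factor was left out too, and the lone sample was assumed to vary like the others. Apart from the number of genes tested, the cause of these differences was not tested. Pearson's r of the doxycycline ratios, -0.0608, was 0.00899 with a minimum of 20 reads, -0.222 with 500 and -0.129 after thinning; the cause was not tested.

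Of 21 list medians outside the central 95%, 19 were outside on the same side with total counts, 21 with median-of-ratios factors, 16 after thinning, and 13 with a minimum of 100 reads, where 2 had no value. Of 111 named ratios at 2-fold, 86 were so on the same side with total counts, 108 with median-of-ratios factors, 110 with the upper quartile and 108 with a pseudocount of 1 CPM. CAPRIN1 in EXOSC10 over IgG with doxycycline reversed, to 1.01 with total counts, by the shift of all ratios. The planned count-model tests were not run because the table holds no counts. Depth limits the genes with few reads: NDC80, with 5 reads in the untreated EXOSC10 library, had an interval from 2.37 to 5.26.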

Other observations

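The genes in this part were chosen after their values were seen. RN7SK, a nuclear regulator of transcription elongation, had 496 reads with IgG and 1919 with EXOSC10 untreated (log2 0.97, 0.83 to 1.12), and 1618 and 3209 with doxycycline (-1.02, -1.11 to -0.93). RN7SL1 was at 1.11 and -1.86. With total counts, which add 2.47 to each ratio with doxycycline, both are positive there, and RN7SK is so with the total of non-ribosomal reads as well, which adds 1.04.

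G3BP1 and G3BP2, which encode related stress granule proteins, lay apart. In EXOSC10 over IgG, untreated and with doxycycline, G3BP1 was at 0.76 (0.31 to 1.23) and 0.61 (0.29 to 0.96), and G3BP2 at -1.55 (-1.81 to -1.30) and -2.87 (-3.09 to -2.68). The difference between the genes hardly depends on the scaling, since a scaling shifts the ratios of a pair of libraries alike, apart from the pseudocount.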
